A study of Mus musculus with 12 samples.

How the data were processed

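The series measured RNA of mouse liver on 12 spotted cDNA arrays with 2 colours. The mice lacked hemopexin (Hx-null), haptoglobin (Hp-null) or both plasma proteins (HpHx-null) and were bred, together with wild-type littermates, from doubly heterozygous parents on a mixed background of 2 strains. Per the labels' protocols, livers of at least 5 perfused adults per genotype were pooled, cDNA was made directly from total RNA with Cy3 or Cy5 and an oligo(dT) primer, and each null pool was hybridised 4 times against a pool of wild-type liver with swapped dyes. Nothing in the labels points to more than 1 pool per genotype. The 4 arrays of a genotype were therefore treated as repeated measurements of 1 pair of RNA pools: every p-value below sets 2 pools against the spread between arrays, not genotypes against the spread between mice, and the wild-type pool is 1 control whose own spread is left out. The number of arrays limits the precision of each value.

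The authors deposited 1 table of log ratios, taken here as log2 values, for 31200 spots and 12 arrays. The base of the logarithm, the normalization, the filter on weak spots and the direction of the ratios are not given in the sources used here. Values ran from -2.89 to 3.48, the medians of the 12 columns from -0.20 to 0.22, and their standard deviations from 0.39 to 0.62. Of the spots, 4167 held a value and 27033 held none on any array. A spot with values had them on at least 6 arrays, and an array held 3009 to 4165 values. Neighbouring spots were duplicates of 1 clone, with correlations within an array of 0.90 to 0.98, and were averaged, which left 2151 of 15600 clones.

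Gene names needed an inference, and every gene name given here depends on it. The platform annotation lists 18384 spots with 1 symbol and 514 with several; 12302 spots are unnamed in it. Read by equal spot number, it was contradicted by the values: among 3476 pairs of different clones of the same gene, 63 had both clones measured, against 67.3 by chance, and the values of those pairs correlated at a median of -0.14 over the arrays. After this was seen, 18683 rearrangements of the numbering were scored by the same count (short shifts, and grids of blocks transposed or flipped), of which 177 came to the full reversal. The highest score, 205, belonged to this reversal, in which spot k carries the annotation of spot 31201 minus k; the highest of the others was 121. Scored apart from these, all 15599 shifts of the direct order, long ones included, reached 122 or less and those of the reversed order 118 or less. The highest of 100000 permutations of the measured clones was 79 (permutation p = 1e-05, the smallest they can give). This p takes no account of the search. The permutations also stayed below the highest shifts, so their spread is too narrow and the p too small. Other evidence was then read. The values of the 205 pairs correlated at a median of 0.61 over the arrays. Of 39 clones of 8 abundant liver or housekeeping transcripts, 30 were measured by the reversed numbering and 5 by the direct one, and of 14 clones of gene families restricted to other tissues 0 and 5. Ribosomal proteins separated the 2 numberings less: of 160 clones, 37 were measured by the reversed one and 20 by the direct one. Same-gene pairs among all these clones were part of the scored count, so these numbers partly repeat it. Clones whose entry joins several genes had no part in the search: 155 of their 238 pairs with the same entry were both measured by the reversed numbering and 0 by the direct one. This is nearly the evidence of 1 entry, the joined alpha-globin entry, which made up 190 of the pairs and 153 of those measured; of the other 48 pairs 2 were measured. The reversed numbering was therefore used, and the direct one is an alternative for the counts. Symbols were looked up by Entrez number in a RefSeq table of assembly GRCm38.p6; 9086 of 9192 clones with 1 symbol were found and 0 symbols changed. No coordinates are given, because the sources name no build. By the reversed numbering, 1017 measured clones carried 1 symbol, 65 several and 1069 none. Clones of 1 gene were averaged, which gave 918 named genes among 2052 features, each a named gene or a clone without a single symbol. No gene was named from an entry with several. No spot of the annotation names the deleted genes, so the labels could not be checked against them.

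Each array was centred on its median. The model, fixed before the data were examined, was limma's lmFit and robust eBayes on all 12 arrays with 1 coefficient per genotype and a gene-specific dye term from the labelled dyes, with Benjamini-Hochberg adjustment and a threshold of 0.05. A feature was tested if at least 3 of 4 arrays of each genotype compared held a value, and with an array left out if at least 2 did. Each null was compared with the wild-type pool, the nulls with each other, and the double null with the sum of the single nulls. The rule for named genes, fixed at the same time, took genes with 1 symbol, values on all 4 arrays, an adjusted p below the threshold and 1 sign on all 4 arrays, the 8 largest each way per null and the 4 largest each way per difference whose arrays did not overlap; 2 spot numbers each way where clones have no single symbol; and from each of 37 gene lists up to 4 members past the threshold or, failing that, up to 2 as values. Lists with at least 3 members on all arrays were tested with limma's camera (preset correlation of 0.01, and estimated) and fry.

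A second fit was added after the data were seen. The arrays fell into 2 blocks, read from the sign of their loading on the first component, that did not follow the labelled dyes, and the block replaced the dye term. This choice was made after the features called in trial fits (centred or not, with the labelled dyes, the blocks or neither) had been counted, and the blocks gave the most. Its results are called "with the block term". The sign condition of the naming rule was read there after the block term had been taken out, a change also made after the data were seen. In simulated data with the arrays' own missing values and spread and 200 features changed in Hx-null among 1865, the labelled dyes recovered 59% of those changed by a log2 of 1 and 24% of those changed by 0.5, with 0 other calls; the block term recovered 100% and 81%, with 6 other calls. The simulated dye effect followed the blocks, which favours the block term. It also had the same size on every array. The real loadings within 1 block ran from -0.11 on HpHx-null replicate 3 to -0.43 on Hp-null replicate 4. The 6 other calls therefore need not hold for the real arrays.

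Alternatives covered scaling, the dye term, the replicate number, the arrays fitted, averaging, missing values, fold minimums, moderation, the reading of the ratios and each array left out. The unmoderated test had no dye term and used only the arrays of the genotypes compared, so it changed more than moderation. Differences between dyes or blocks stayed in its spread. Software was R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.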

Results

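RNA of pooled livers from mice without hemopexin (Hx-null), haptoglobin (Hp-null) or both (HpHx-null) was compared with a pool of wild-type liver on 4 two-colour arrays per genotype. Hemopexin binds free heme in plasma and haptoglobin binds free hemoglobin, and the design asks which liver transcripts differ when either or both are missing. The deposited log2 ratios covered 3009 to 4165 of 31200 spots per array, or 2151 clones. Gene names rest on a reversed numbering of the spots inferred from the values, as described under the processing, and no probe for the deleted genes was found in the annotation. The 4 arrays of a genotype measured 1 pair of pools, and each SE below is that of the fitted value, with the spread estimated over all arrays that held a value.

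The direction of the ratios was not settled, so values are given with their deposited sign, as positive or negative ratios. The labels place the null pool in channel 2 of every array and swap its dye on replicates 3 and 4. In Hx-null the 2 arrays of the same labelled dye correlated across spots at 0.81 to 0.83. In Hp-null such arrays correlated at -0.77 to -0.55, and in HpHx-null at -0.63 to -0.23. The first component held 70.7% of the sum of squares and split the arrays into 2 blocks of 6 arrays, 2 of each block in every genotype. Correlations were 0.46 to 0.89 within a block and -0.79 to -0.14 between blocks. The block and the labelled dye differed on 4 arrays, replicates 1 and 3 of Hp-null and 2 and 4 of HpHx-null. If the values are null over wild-type, as the order of the channels would have it, a positive ratio means more RNA in the null pool. Only that order speaks for this reading. The planned rule asked for lower deleted genes in their nulls and for positive correlations between opposite labelled dyes within a genotype. The first could not be checked. The second was not met as deposited, where the median correlation was negative. With the arrays turned by the labelled dyes, as for Cy5 over Cy3, 0 features passed in all 7 comparisons.

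**Figure D1:**
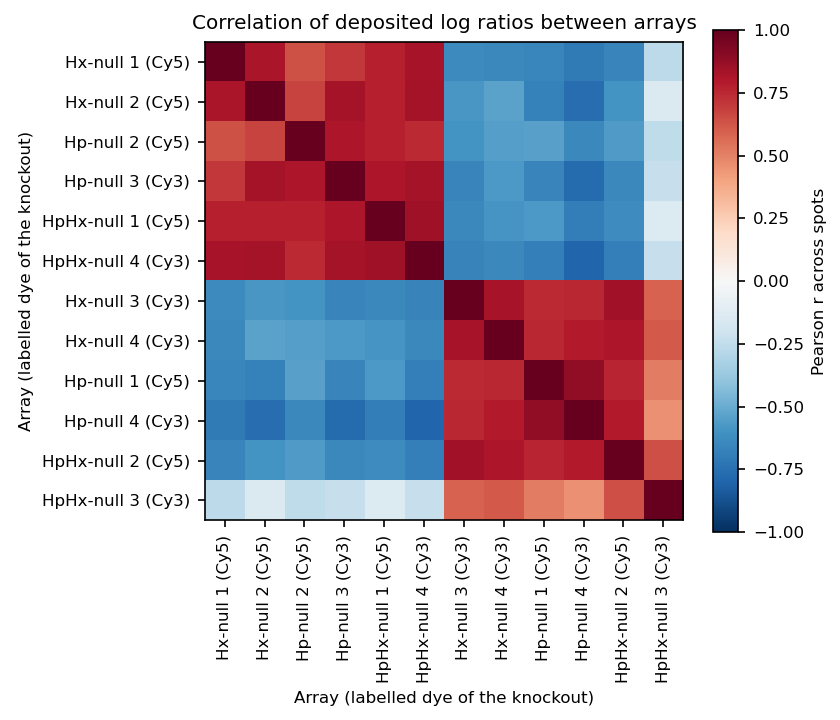
Pearson correlation across spots between the deposited log ratios of each pair of the 12 arrays, ordered by block, with the labelled dye of the null pool in brackets. Correlations lie between 0.46 and 0.89 within the 2 blocks and between -0.79 and -0.14 across them.

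In Hx-null against wild-type, 12 of 1865 features, each a named gene or a clone without a single symbol, passed with the labelled dyes (limma, adjusted p < 0.05), and all 12 ratios were positive, from 0.95 to 1.49 on the log2 scale. Of these features, 8 were clones of 1 annotation entry that joins the adult alpha-globin genes with a histone gene, so that no single gene can be named from it; 3 had no symbol and 1 was named Wdr7 (log2 ratio 1.21, SE 0.14, adjusted p = 0.00886). Wdr7 was measured on 3 arrays of Hx-null, outside the naming rule, and is named after its value was seen. In all, 16 clones of the joined entry were tested. The entry had 18 measured clones, whose median log2 ratio was 1.0 in Hx-null, -0.12 in Hp-null and 0.40 in HpHx-null, with 3 clones below 0.2 in Hx-null. These 3 clones, at 0.05, 0.06 and 0.17, were the only clones of the entry measured on all 12 arrays. Every clone with a larger ratio lacked a value on at least 1 array. Spot 11831 of this entry had a log2 ratio of 1.03 ± 0.23 (SD, n = 4 arrays; SE 0.13, limma adjusted p = 0.00886), positive on 4 of 4 arrays, and spot 8627, without a symbol, 1.02 ± 0.27 (SD, n = 4 arrays; SE 0.14, limma adjusted p = 0.00971). Because many of these clones can detect the same transcript, the 12 features are not 12 separate findings. Left without replicate 1, 2 or 3 of Hx-null, 0 features passed, and only 2 of the 12 were measured on replicate 4. The unmoderated test called 0, the replicate block 0, values as deposited 7, quantile scaling 6 and a fit to the arrays of Hx-null alone 132. Among all 1865 features, 70 reached an unadjusted p under 0.05 in limma with the labelled dyes, against 93.25 by chance.

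**Figure D2:**
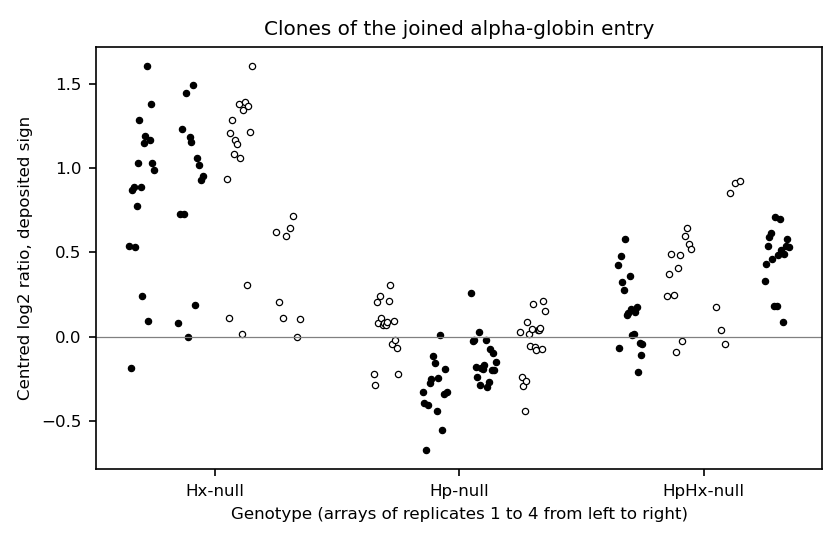
Centred log2 ratios with deposited sign of the 18 measured clones of the joined alpha-globin entry, 1 point per clone and array, with filled and open points for the 2 blocks of arrays. Medians over clones were 1.0 in Hx-null, -0.12 in Hp-null and 0.40 in HpHx-null.

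In Hx-null 38 features passed with the block term, 34 of them positive, and all 12 above were among them. Bhmt, which remethylates homocysteine, had a log2 ratio of 0.65 (SE 0.09, adjusted p = 0.00109), positive on 2 of 4 arrays before the block term was taken out, and Bche, butyrylcholinesterase, 0.72 (SE 0.16, adjusted p = 0.0257), positive on 4 of 4. Smap1 stood at 0.50 (SE 0.09, adjusted p = 0.0109). The 4 negative ratios included Gstp1, a glutathione transferase, at -0.87 (SE 0.13, adjusted p = 0.00115) and Nudt7, a peroxisomal hydrolase, at -0.71 (SE 0.10, adjusted p = 0.00115). Gstp1 and Nudt7 belong to the list of male-biased liver genes, of which 3 members were tested. The third, Serpina1e, had a mean ratio of the opposite, positive sign and did not pass, though all 3 did when adjusted over the list alone. In the list of amino acid breakdown 1 of 4 members passed (2 adjusted over the list alone), in the antioxidant list 1 of 9 (2 adjusted over the list alone), and among 22 ribosomal proteins 0 (0 adjusted over the list alone). With the labelled dyes none of these named genes passed; Nudt7 came nearest (adjusted p = 0.0642), with negative ratios on 4 of 4 arrays. Left without Hx-null replicate 2 or 3 the count was 23, without HpHx-null replicate 3 it was 87, and values as deposited gave 82 and quantile scaling 59.

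In Hp-null against wild-type, 0 of 2017 features passed with the labelled dyes in limma, 49 reached an unadjusted p under 0.05, against 100.85 by chance, and the unmoderated test also called 0. As a list, ribosomal proteins were shifted to negative ratios (median log2 -0.16 over 24 members, camera adjusted p = 0.00636), as were antioxidant and NRF2 target genes (median -0.26 over 9, adjusted p = 0.00636), iron handling (median -0.25 over 4, adjusted p = 0.0178) and ER stress and heat shock (median -0.15 over 6, adjusted p = 0.0178), while oxidative phosphorylation was not (adjusted p = 0.180). With an estimated correlation none of the 5 lists passed: the adjusted p was 0.071 for ribosomal proteins, iron handling and ER stress and 0.234 for the antioxidant list. By fry none passed either, with an adjusted p of 0.0603 for ribosomal proteins and iron handling, 0.132 for ER stress and 0.389 for the antioxidant list. The medians of these 4 lists were negative under all 3 scalings, from -0.16 to -0.13 for ribosomal proteins and from -0.15 to -0.052 for ER stress. Camera used the members measured on all arrays, which were 13, 5, 3 and 4 of these lists. Adjusted over the list alone, 1 ribosomal protein passed and 0 members of the other lists.

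In Hp-null 54 features passed with the block term, 17 positive and 37 negative. Ftl1, the ferritin light chain, had a ratio of -0.94 (SE 0.07, adjusted p = 1.02e-05), a 1.91-fold size, with negative ratios on 4 of 4 arrays. With the arrays turned by the labelled dyes, Ftl1 in Hp-null against wild-type was -0.064. All 6 Ftl1 clones were negative in Hp-null, from -1.19 to -0.61. With the labelled dyes the same ratio had an SE of 0.32 and did not pass (adjusted p = 0.999). Of the 4 iron handling genes tested, Ftl1 alone passed (2 adjusted over the list alone); the transferrin receptor Tfrc had a ratio of -0.02 (SE 0.08). Of 9 antioxidant genes 2 passed, both negative (6 adjusted over the list alone): Gstp1 at -0.59 (SE 0.13, adjusted p = 0.0323) and Gstm1 at -0.46 (SE 0.11, adjusted p = 0.0423). Gstm2 of the same list had a ratio of -0.25 (adjusted p = 0.306). Mgst1, a microsomal glutathione transferase outside the list, stood at -0.70 (SE 0.14, adjusted p = 0.0194). Of 24 ribosomal proteins 4 passed, all negative (6 adjusted over the list alone), among them Rps2 at -0.80 (SE 0.16, adjusted p = 0.021). Of 6 ER stress genes 1 passed (1 adjusted over the list alone), the chaperone Hspa5 at -0.54 (adjusted p = 0.0363). Of 19 genes of oxidative phosphorylation 1 passed (5 adjusted over the list alone), Cox7c at -0.53 (adjusted p = 0.0142), and of 3 secretory products 1 (1 adjusted over the list alone), Ttr at -0.55 (adjusted p = 0.0404). By camera with the block term the same 4 lists had negative ratios (adjusted p = 0.00759 for iron handling, 0.000596 for antioxidant genes, 0.0210 for ER stress and 0.0312 for ribosomal proteins). With an estimated correlation none passed (adjusted p = 0.0590 for the first 3 and 0.122 for ribosomal proteins), while by fry all 4 did, at 0.000195, 0.00824, 0.00725 and 0.0138. Positive ratios included Anapc4 at 0.85 (SE 0.13, adjusted p = 0.00606), the sphingolipid enzyme Cers4 at 0.76 (SE 0.17, adjusted p = 0.0423) and Cdo1, cysteine dioxygenase, at 0.64 (SE 0.08, adjusted p = 0.00322). Left without Hp-null replicate 1, the count fell to 8, without replicate 2 to 12, without Hx-null replicate 2 to 35 and without HpHx-null replicate 4 to 22. Without Hp-null replicate 3 it was 105, and a 1.5-fold minimum left 22. Values as deposited gave 38 positive and 46 negative features, and quantile scaling 20 and 15.

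**Figure D3:**
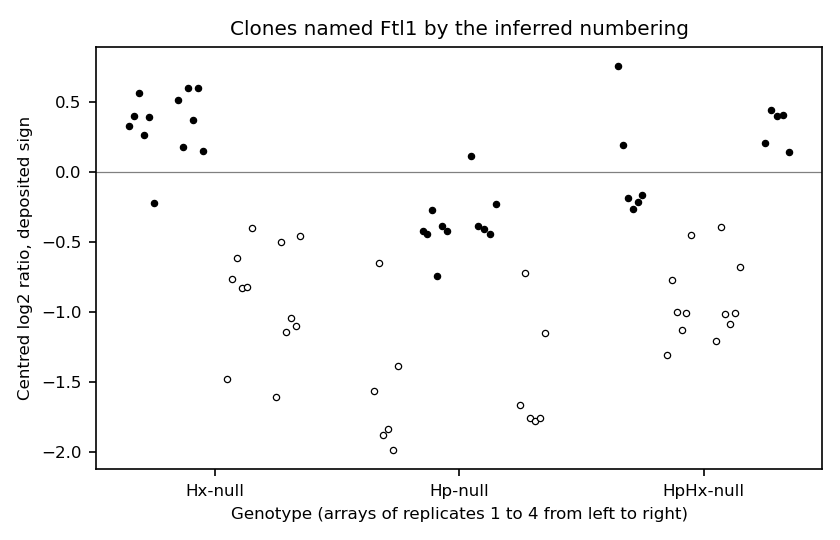
Centred log2 ratios with deposited sign of the 6 clones named Ftl1 by the inferred numbering, 1 point per clone and array, with filled and open points for the 2 blocks of arrays. Means over the 4 Hp-null arrays run from -1.19 to -0.61 per clone.

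In HpHx-null against wild-type, 0 of 1711 features passed with the labelled dyes in limma and 100 reached an unadjusted p under 0.05, against 85.55 by chance; the unmoderated test called 0. A fit with no dye term called 7, one on clones measured on all 12 arrays 7, and one without Hp-null replicate 4 called 4. With the block term 91 features passed, 86 of them positive. Serpina1e, a liver serine protease inhibitor, had a ratio of 1.37 (SE 0.18, adjusted p = 0.00356), but -0.26 with the arrays turned by the labelled dyes. Further positive ratios included Rbbp5 at 0.97 (SE 0.14, adjusted p = 0.00535), Prex2 at 0.94 (SE 0.19, adjusted p = 0.0149) and Ttc3 at 0.86 (SE 0.14, adjusted p = 0.00673). Hebp1, a heme-binding protein and the single measured gene of the heme breakdown and uptake list, stood at 0.73 (SE 0.15, adjusted p = 0.0131). Of 5 genes of amino acid breakdown 2 passed, both positive (3 adjusted over the list alone): Mat1a at 0.57 (SE 0.10, adjusted p = 0.0108) and Bhmt at 0.42 (SE 0.10, adjusted p = 0.0362). Of 2 macrophage genes tested, the receptor Fcgr1 passed at 0.52 (adjusted p = 0.0158) and Fcer1g, at -0.08 (adjusted p = 0.898), did not. Negative ratios, 5 in all, included Gstp1 at -0.92 (SE 0.13, adjusted p = 0.00356), Nudt7 at -0.63 (SE 0.12, adjusted p = 0.0102) and Ftl1 at -0.38 (SE 0.07, adjusted p = 0.0093). As a list, iron handling had negative ratios by fry (adjusted p = 0.0116) but did not pass by camera (adjusted p = 0.0614, with an estimated correlation 0.313). Of 4 iron handling genes Ftl1 alone passed (1 adjusted over the list alone). Of 7 antioxidant genes 2 passed (4 adjusted over the list alone), Gstp1 and, on the positive side, Cat at 0.55 (SE 0.13, adjusted p = 0.0362). Of 18 genes of oxidative phosphorylation 1 passed (3 adjusted over the list alone), Atp5md at 0.78 (SE 0.12, adjusted p = 0.00562). All 3 male-biased genes passed, 1 positive and 2 negative (3 adjusted over the list alone). Left without HpHx-null replicate 3, 33 features passed, and without replicate 4, 51. Replicate 3 was unlike the other arrays. Its loading on the first component, -0.11, was the smallest in size of all arrays, and it held the fewest values. Before the block term was taken out, it had the highest HpHx-null ratio for Ttc3 (1.29) and Atp5md (1.06), but not for Serpina1e, Rbbp5 or Prex2. That order includes the block difference. Against replicate 2, of the same block, replicate 3 was higher for Serpina1e (0.42 against -0.11), Rbbp5 (1.25 against 0.66) and Prex2 (0.49 against 0.05). These genes may therefore lean on replicate 3 as well.

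Between the nulls, 11 of 1848 features differed between Hp-null and Hx-null with the labelled dyes, all lower in signed ratio in Hp-null, by -1.53 to -1.17. All 11 were among the 12 features of Hx-null, and 7 were clones of the joined alpha-globin entry. Spot 11831 differed by -1.17 (SE 0.18, limma adjusted p = 0.0365) and spot 8627 by -1.22 (SE 0.20, limma adjusted p = 0.0365). The count of 11 depended on the arrays: 0 features differed without Hx-null replicate 1, 2 or 3, without any 1 of the 4 arrays of Hp-null, or without HpHx-null replicate 2 or 4. It was 0 also with values as deposited, with quantile scaling or with the replicate block, and the unmoderated test called 1. In limma with the labelled dyes 33 features reached an unadjusted p under 0.05, against 92.4 by chance. With the block term 20 features differed, among them Ftl1 by -0.66 (SE 0.10, adjusted p = 0.00208) and Agbl5, a carboxypeptidase, by -0.73 (SE 0.13, adjusted p = 0.00709), and 53 differed without Hp-null replicate 3. As a list, iron handling was lower in Hp-null with the block term (camera adjusted p = 0.0323, by fry 0.0132, with an estimated correlation 0.233). Between HpHx-null and Hx-null 0 of 1654 features passed in limma with the labelled dyes, with 16 at an unadjusted p under 0.05; the block term gave 3 features, of which 2 were clones of the joined entry with lower signed ratios in HpHx-null. Quantile scaling left 0 of the 3 and values as deposited gave 7. Replicate 1, 2 or 3 of Hx-null, 2 of Hp-null, or 1 or 2 of HpHx-null, each left out, lowered the count to 0 or 1. Between HpHx-null and Hp-null 0 of 1690 features passed in limma with either term (6 with the block term without HpHx-null replicate 1), with 37 at an unadjusted p under 0.05 with the labelled dyes and 214 with the block term. The unmoderated test called 0 features in both of these comparisons.

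The double null departed from the sum of the single nulls in 0 of 1646 features with the labelled dyes in limma, with 18 at an unadjusted p under 0.05 and 0 by the unmoderated test. With the block term 1 feature passed. It was Ftl1, whose ratio of -0.38 in HpHx-null lay 0.84 (SE 0.12, adjusted p = 0.0162) above the sum of -0.28 in Hx-null and -0.94 in Hp-null. This call was lost when replicate 4 of Hx-null, replicate 1 or 2 of Hp-null, or replicate 2, 3 or 4 of HpHx-null was left out, and with values as deposited or quantile scaling. It was also lost when the loadings replaced the blocks, a fit in which the block difference varies in size between arrays. Left without replicate 1, 2 or 3 of Hx-null, 2 features passed. The wild-type pool does not cancel in this contrast. A deviation of that pool alone can therefore set Ftl1, or the lists below, apart from the sum. As lists, antioxidant genes (camera adjusted p = 0.0347) and ribosomal proteins (adjusted p = 0.0347) lay above the sum with the labelled dyes. With an estimated correlation the adjusted p was 0.428 and 0.184, and by fry 0.825 and 0.586. The block term gave camera adjusted p of 0.00306 and 0.109, 0.137 and 0.223 with an estimated correlation, and 0.0822 and 0.124 by fry.

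Of the 37 lists, 10 had no measured member, among them the acute phase proteins and cytochrome P450 genes, which were therefore not analysed here. The metallothioneins Mt1 and Mt2 had ratios between -0.08 and 0.07 in all 3 nulls, and Urod of heme synthesis between -0.01 and 0.08. The erythroid genes Tfrc and Ermap, measured beside the joined alpha-globin entry, had ratios in Hx-null of 0.01 (SE 0.13) and 0.36 (SE 0.68) with the labelled dyes, and of 0.01 (SE 0.07) and 0.06 (SE 0.15) with the block term; neither passed. The neutrophil genes Ltf and Csf3r did not pass in any null (1 of the 2 when adjusted over the list alone, in Hx-null with the block term).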

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

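The tests of explanations and the counts of splits in this part were chosen after the results were seen. Hp-null replicate 2 held 3522 spots with a value, far from the other arrays of its genotype. Tomm70a on Hx-null replicate 3, at a log2 ratio of 0.57, stood apart from the other arrays of Hx-null. Chance sets about 1 in 20 groups apart in this way, and 47 groups were looked at, with 2 such values. By a test of the difference itself, Hp-null was lower in signed ratio than Hx-null for spot 11831 (by -1.17) and spot 8627 (by -1.22) with the labelled dyes, and for Agbl5 (by -0.73) and Ftl1 (by -0.66) with the block term. Ftl1 in the double null lay 0.84 above the sum of the single nulls with the block term, a contrast in which the wild-type pool does not cancel.

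The first pattern is the pair of blocks of arrays that part from the labelled dyes. If the values had been left as Cy5 over Cy3 and the blocks were the true dye orientation, the mean over both blocks would be a dye effect shared by the genotypes. Its correlation, corrected for array noise, was 0.276 between Hx-null and Hp-null and 0.419 between Hp-null and HpHx-null. Between Hx-null and HpHx-null it was 0.992. The low values speak against this reading and the high one does not. The block difference was not of equal size on all arrays, so part of it stays in these means, and the test cannot decide. Crossed dye labels on 4 arrays, with values already turned to 1 direction and a dye effect common to all arrays, cannot be told apart from another cause of the blocks. The difference between blocks had a lowest corrected correlation of 0.951, but the blocks were read from the first component of the same values, so this restates how they were defined. Nothing in the labels can settle which arrays are crossed. No biological explanation was tested, because each genotype has 2 arrays in either block.

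The second pattern is the positive ratios of the joined alpha-globin clones in Hx-null. Loss of hemopexin alone would give both nulls that lack it the same ratio; HpHx-null less Hx-null had a median of -0.55 (SD 0.35 over clones), but with 1 pool of each this spread is technical and decides nothing. Blood or erythroid cells left in the Hx-null pool may account for the ratios and cannot be told apart from an effect of the genotype: the only clone of the joined beta-globin entry had a ratio of 1.36, but on 1 array of Hx-null. The livers were perfused per the labels, and the erythroid genes Tfrc and Ermap, of which Tfrc is also made by liver, had ratios of 0.01 (SE 0.13) and 0.36 (SE 0.68) with the labelled dyes and 0.01 and 0.06 with the block term. With the labelled dyes Ermap was too imprecise to decide. With the block term its SE, given above, was smaller, and its ratio lay well below those of the called clones. These are single genes rather than a set, so they do not decide. Both explanations stay open.

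Other groupings of the arrays were counted for each comparison. Against wild-type the signs of the 4 arrays can be turned in 8 ways, too few for a share under 0.05. With the labelled dyes, Hx-null gave 12 features and the highest other pattern 10 (1 of 8 patterns as large), Hp-null 0 and 0 (8 of 8), and HpHx-null 0 and 0 (8 of 8). The block term gave 38 and 241 (2 of 8), 54 and 966 (3 of 8), and 91 and 1 (1 of 8). Between nulls, 35 splits were made. Each count of splits or patterns includes the real one. With the labelled dyes chance cannot be excluded for Hp-null and Hx-null (11, highest other 1008, 2 of 35). There the only other split as large was the 2 blocks of arrays, so the share rests on that structure. With the block term chance cannot be excluded for HpHx-null and Hx-null (3, highest other 14, 2 of 35) or Hp-null and Hx-null (20, highest other 111, 3 of 35). For HpHx-null and Hx-null the only other split as large was again the 2 blocks. Nor can chance be excluded for the double null against the sum with the block term (1, highest other 24, 13 of 100 drawn splits). A count of 0 is matched by every split by construction, so the share tests nothing there: the other values were 279 at most for HpHx-null and Hx-null (35 of 35), 914 for HpHx-null and Hp-null (35 of 35; 111 and 35 of 35 with the block term) and 978 for the double null (100 of 100). The same holds for the 8 of 8 above. The highest splits between nulls with the labelled dyes were the 2 blocks of arrays. So were the patterns that gave 241 in Hx-null and 966 in Hp-null with the block term, and the splits that gave 14 and, for Hp-null and Hx-null, 111. These point to that structure of the samples.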

How the results depend on the processing

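The alternatives with the block term, the loadings, the arrays turned by blocks and the direct numbering were chosen after seeing the data; the others were chosen before. Where a count moved, the cause was not tested, except that fits on fewer arrays or clones test less. Counts below are of features past the threshold, and those not given stayed within 1.5 times the reported count. Signal over background is not in the deposited values, so the limit set by weak spots is unknown.

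With the labelled dyes, values as deposited gave 7 in Hx-null and 0 for Hp-null less Hx-null, and quantile scaling 6 and 0. No dye term gave 7 in HpHx-null. The replicate block gave 0 and 0; with the mean of each genotype taken out, 12 pairs of arrays with the same number correlated from -0.87 to 0.86, so the numbers do not pair arrays. Each comparison on its own arrays gave 132 in Hx-null and 0 for Hp-null less Hx-null. Each spot tested on its own gave 0 for that difference. Only clones on all 12 arrays gave 0 in Hx-null, 7 in HpHx-null and 0 for the difference. That setting left out every clone of the joined alpha-globin entry that passed in Hx-null. The unmoderated test, on the arrays of each comparison and without a dye term, gave 0 in Hx-null and 1 for the difference. Arrays averaged to 1 value per pool, with a size of at least 1 and no test, gave 2 in Hp-null and 2 in HpHx-null. Only arrays labelled with the knockout in Cy5 gave 0 in Hx-null and 0 for the difference, as did only those in Cy3. Arrays turned by the labelled dyes gave 0 and 0, and the median correlation of opposite labelled dyes within a genotype, -0.557 as deposited, became 0.557. The planned rule for the direction asked for a positive correlation there.

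The block term in place of the labelled dyes gave 38 in Hx-null, 54 in Hp-null, 91 in HpHx-null, 3 for HpHx-null less Hx-null, 20 for Hp-null less Hx-null and 1 for the double null against the sum. The loadings gave 69, 96, 91, 3 and 18 for the first 5 of these, and 0 for the last. Arrays turned by the blocks gave 922, 1200 and 760 in the 3 nulls. Under the block term, values as deposited gave 82 in Hx-null, 84 in Hp-null, 7 for HpHx-null less Hx-null and 0 for the double null, and quantile scaling 59, 35, 0 and 0. The share of positive features was 31.5% in Hp-null when centred, 45.2% as deposited and 57.1% with quantile scaling; in Hx-null it was 89.5% when centred and 78.0% with quantile scaling; for HpHx-null less Hx-null it was 0% when centred and 14.3% as deposited. Each spot on its own gave 3 for the double null, a 1.5-fold minimum 22 in Hp-null and the direct numbering 2 for the double null. Of 4 lists shifted in Hp-null, 0 held with an estimated correlation, and 0 with the block term and an estimated correlation.

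Some named genes turned sign. On arrays with the knockout in Cy5 alone Hnrnpr in Hx-null against wild-type was -0.00392. On those in Cy3 alone Bhmt in Hx-null was -0.29, and Hp-null less Hx-null was 0.31 for Agbl5 and 0.023 for Ftl1. Without Hp-null replicate 1, Rcc2 in Hp-null was -0.082 with the labelled dyes, and with each array left out it ranged from there to 0.92 in that fit. Rcc2 was named with the block term, and single genes were not followed there with arrays left out. With the arrays turned by the labelled dyes the ratios in Hx-null were -0.27 for Trmt5, -0.55 for Hnrnpr, -0.18 for Smap1, -0.046 for Tomm70a, 0.64 for Gstp1 and 0.11 for Nudt7. In Hp-null they were -0.056 for Cdo1, 0.020 for Mgst1, 0.012 for Gstp1 and 0.016 for Ttr. In HpHx-null they were -0.26 for Serpina1e, -0.30 for Rbbp5, -0.087 for Prex2, -0.22 for Ttc3, -0.063 for Nfatc4, -0.27 for Ak4, -0.00194 for Anapc7 in HpHx-null against wild-type and -0.17 for Atp5md. Ftl1 in the double null against the sum was -0.64.

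With each array left out in turn, the labelled dyes gave 0 to 13 in Hx-null, 0 to 0 in Hp-null, 0 to 4 in HpHx-null and 0 to 11 for Hp-null less Hx-null, and 0 for the other comparisons. The block term gave 23 to 87 in Hx-null, 8 to 105 in Hp-null, 33 to 96 in HpHx-null, 0 to 3 for HpHx-null less Hx-null, 0 to 6 for HpHx-null less Hp-null, 15 to 53 for Hp-null less Hx-null and 0 to 2 for the double null against the sum.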

Other observations

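The tests in this part were chosen after the results were seen. Across the 1129 features measured on all arrays, which are not independent replicates, the mean ratios over both blocks correlated at 0.70 between Hx-null and HpHx-null, at 0.30 between Hp-null and HpHx-null and at 0.19 between Hx-null and Hp-null; array noise alone gave -0.06 to 0.06 in simulation. All 3 nulls share the wild-type pool, whose own deviation adds the same covariance to every pair. The block difference was also not of equal size on all arrays, with loadings within 1 block from -0.11 to -0.43. Part of it therefore stays in these means and can raise or lower a covariance, and the simulation left it out. The correlations do not separate it from an effect shared by genotypes. The covariance was 0.0227 (95% interval over features 0.0184 to 0.0274) for Hx-null and HpHx-null, 0.0105 (0.0069 to 0.0142) for Hp-null and HpHx-null and 0.00504 (0.00269 to 0.00752) for Hx-null and Hp-null. Without HpHx-null replicate 3 the first was 0.0174 and the second 0.0107. A count with the block term found 14 positive features shared by Hx-null and HpHx-null, against 1.28 for independent calls, and 2 negative against 0.00902. Hp-null and HpHx-null shared 8 positive against 0.556 and 3 negative against 0.0941, and Hx-null and Hp-null 2 positive against 0.249 and 1 negative against 0.0756. All these counts include what the shared wild-type pool brings and what a block term of equal size leaves of the block difference. The expected counts also take features as independent, yet spots 11139, 27445 and 29419, shared by Hx-null and HpHx-null, belong to the joined alpha-globin entry. Each feature has 1 spread estimate for all nulls, so its calls are not independent either.

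Smap1 had block-term ratios of 0.50 in Hx-null, 0.64 in Hp-null and 0.59 in HpHx-null, and Gstp1 -0.87, -0.59 and -0.92, each past the threshold in all 3 nulls. Because 1 wild-type pool serves all 3, such a ratio can also come from that pool. Further genes of HpHx-null were Ak4, an adenylate kinase, at 0.80, and Atp5md, a subunit of ATP synthase, at 0.78. For both, HpHx-null replicate 3 held the highest ratio of that genotype (1.42 and 1.06).

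A hypothesis is that chromatin of the 129Sv strain carried along with a deleted gene shifts its neighbours. For the 20 measured genes nearest to Hp, placed by the inferred names, the mean size of the block-term ratio in Hp-null lay at percentile 78.2 of other such windows, and for those nearest to Hpx in Hx-null at percentile 18.5. In HpHx-null the windows lay at percentile 84.7 for Hp and 36.8 for Hpx. Near Hp 1 gene passed the threshold in Hp-null and 2 in HpHx-null, and near Hpx 0. All 4 windows lie within the spread of other windows, and a shift of a few close neighbours need not show in such a mean, so the hypothesis stays open for both genes.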
